A study of Drosophila melanogaster with 6 samples.

How the data were processed

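Total RNA from whole Drosophila melanogaster embryos was measured on 6 one-colour Affymetrix Drosophila Genome 2.0 arrays, 3 from wild type embryos and 3 from trh null embryos. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on columns, then amplified from its 3' end and labelled with biotin. Such labelling starts at the poly-A tail, so probe sets far from the 3' end lose signal first when RNA is short. Per the submitters' processing notes, RMA and Partek were used, without versions. RMA as generally run corrects background, makes the quantiles of all arrays equal and summarises the probes of a probe set. It can therefore hide a change shared by all transcripts. The deposited values were on a log2 scale per the range of the deposited table and the named RMA method, with base 2 inferred and not stated. They were used as deposited. The scanner files were not analysed here.

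Genotype was taken from the genotype label of each sample. The deposited table held 18952 probe sets, of which 183 Affymetrix control probe sets were left out of the tests, leaving 18769. Gene names came from the platform annotation given with the data, which named 1 gene for 13646 of these probe sets, several for 402 and none for 4721. A probe set with several names was used for no gene. Of the probe sets with 1 name, 13543 matched by gene identifier the RefSeq gene table of the assembly Release 6 plus ISO1 MT, and no symbol changed. That table gave chromosome arms and gene lengths only. A gene was represented by the probe set, naming it alone, with the highest mean over the 6 arrays, which gave 11981 genes, and 1094 of them had more than 1 such probe set. For 13 genes, probe sets passed the test in both directions, and the text says so where such a gene is named. No 2 arrays held identical values.

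Each probe set was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the 18769 probe sets, with a threshold of 0.05. Fold changes are differences of mean log2 signal, so signal near background understates the change of dim genes. In the text, "rose", "fell" and "passed" refer to this threshold, with the direction of trh null relative to wild type. For 30 gene lists, fixed from general knowledge before the data were examined, the members that passed were counted over all probe sets and adjusted over the list alone. Each list was tested with limma's camera (preset correlation 0.01, 1 probe set per gene, adjusted over the 30 lists). The lists covered tracheal patterning, fusion cells and luminal matrix, other trh tissues (salivary duct and gland, posterior spiracle), epidermis and cuticle, other tissues, stage-dependent programs and metabolism. A family pattern in a list took symbols followed by a digit or capital letter, so the Ccp84A genes and Twdlbeta fell outside the cuticle protein list. For trh, stumps, pnt, rho and some other list members the annotation used here named no probe set singly, and these genes were not analysed here.

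The genes to be named were set by a rule before the data were examined. It took the 12 named and 3 numbered genes with the largest fall and the largest rise among genes that passed and whose 3 values of one genotype all lay on one side of the other 3. It also took up to 4 members per list that passed (2 members where none did), and every member of the patterning and branching list. Outside this rule kkv, uif, Osi2, Osi6, Osi7, Osi14, Cpr78E, twi, pnr, the second probe sets of dysf, uif and svp, and the genes named only in the observations were chosen after their values were seen. Single control values were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 arrays against 3. Simulated data took the mean of each probe set, 1 SD pooled over both genotypes and independent noise, with 200 of 18769 probe sets changed. There the fit recovered 70.5% of changes of 1 on the log2 scale with 6 false calls, and 91.5% of changes of 2 with 5 false calls. The real arrays differed in spread between genotypes and more probe sets passed, so these rates may not hold for them.

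The alternatives were another prior (trend and robust), unmoderated variances, array weights, quantile normalization, median centring, cyclic loess, leaving out the 40% dimmest probe sets, the mean over a gene's probe sets, the replicate number as a block, adjusted p under 0.01, an unadjusted p, a 2-fold threshold, camera with an estimated correlation, the rotation test fry, and leaving out each array in turn. Removal of the trend on gene length was added after the control probe sets had been seen. Tables were joined with pandas 2.3.3 in Python 3.11.15 and figures were drawn with matplotlib 3.10.9. For arrays the number of replicates, here 3 per genotype, limits the precision.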

Results

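RNA levels were measured in whole Drosophila melanogaster embryos of 2 genotypes, wild type and trh null, with 3 arrays per genotype. The trh gene (trachealess) encodes a bHLH-PAS transcription factor that is made in tracheal, salivary duct and filzkörper primordia. According to the series title, the comparison asks how far tracheal genes depend on trh in the embryo. Embryos were collected over 8 h and aged for a further 11 h, and the labels place them at stages 11 to 16. For the wild type arrays the sample description gives stage 17 as the last stage instead. All embryos passed through a biosorter, and trh null embryos were recognised by the missing GFP of the balancer chromosome. The arrays carried 18769 probe sets that were not controls, and the median log2 signal per array lay between 6.16 and 6.22. No probe set was named for trh alone in the platform table, so the level of the trh transcript was not analysed here. Nothing in the labels says whether the arrays of a genotype came from separate cages or collections, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

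Among the largest falls in trh null embryos were those of single Osiris genes and of uncharacterised genes. Osi19 was 76.2-fold lower, from 12.78 ± 0.24 to 6.53 ± 0.94 on the log2 scale (SD, n = 3 arrays), and Osi20, Osi18 and Osi15 were 65.1-fold, 62.9-fold and 48.8-fold lower. Osi20 varied between trh null arrays (7.10 ± 1.15, SD, n = 3), and without trh null replicate 1 it fell by 5.39 in place of 6.03 on the log2 scale. CG31559 was 72.8-fold lower (a fall by 6.19 on the log2 scale, SE 0.10, limma adjusted p = 8.37e-06), and apn, which encodes a transmembrane protein of tracheal tube cells, was 42.7-fold lower (SE 0.27 on the log2 scale, limma adjusted p = 0.000288). Rises were smaller. CG32299 rose by 3.40 (SE 0.10), CG1894 by 3.04 (SE 0.26) and CG32073 by 2.76 (SE 0.19) on the log2 scale, and Hsc70-2, a cytosolic Hsp70 relative, rose 5.70-fold from 5.21 ± 0.07 to 7.73 ± 0.04 (SD, n = 3 arrays).

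In limma's moderated test with Benjamini-Hochberg adjustment, 2219 of 18769 probe sets changed at an adjusted p under 0.05, of which 1161 rose and 1058 fell in trh null embryos. At least 1.5-fold change was seen for 1492 of them, 742 higher and 750 lower. At least 4-fold change was seen for 117, of which 35 rose and 82 fell. Counted as genes, each by the brightest probe set naming it alone, 814 rose and 876 fell among 11981. The remaining named genes with the largest falls were Drsl5, a drosomycin-like peptide gene (30.4-fold), Twdlbeta, a Tweedle cuticle protein gene (26.8-fold), Cpr64Ad, a chitin-binding cuticle protein gene (23.0-fold), tpr (21.4-fold), Cht5, a chitinase gene (19.7-fold), Osi9 (17.5-fold) and ry, the xanthine dehydrogenase gene (16.3-fold). CG12009 and CG11786 fell by 4.99 and 4.29 on the log2 scale. The remaining named genes with the largest rises were Sema1a, a semaphorin (5.70-fold), Blimp-1, a zinc finger repressor (5.09-fold), ninaD, a scavenger receptor (4.99-fold), the lysozyme gene LysX (4.97-fold), Oat, for ornithine aminotransferase (4.72-fold), the glutathione transferase genes GstD4 (4.70-fold) and GstD7 (4.15-fold), DopEcR (4.67-fold), Ugt37A2 (4.46-fold), kek5 (4.24-fold) and Cyp6a16 (4.09-fold). Twdlbeta varied in both genotypes (10.59 ± 1.18 and 5.84 ± 1.61, SD, n = 3). Its log2 difference of -4.74 was -5.38 without wild type replicate 2 and -5.67 without trh null replicate 3, and with any other array left out its call was lost (limma adjusted p from 0.0628 to 0.1003). The calls for Sema1a and Cpr64Ad were lost without trh null replicate 2 (limma adjusted p = 0.0685 and 0.0556), and that for Sema1a also without trh null replicate 3 (adjusted p = 0.0726). The count changed when 1 array was left out. This also takes away 1 of 3 replicates of a genotype, so a loss need not point at that array. The same holds for each call described as lost with an array left out. Without wild type replicate 2, 5001 probe sets passed, among them all 2219 with the same sign, and leaving out trh null replicate 1, 2 or 3 gave 845, 736 and 704.

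Among genes of tracheal development, btl, the FGF receptor of tracheal cells, fell 2.60-fold in trh null embryos, from 6.98 ± 0.20 to 5.60 ± 0.02 on the log2 scale (SD, n = 3 arrays; limma adjusted p = 0.00153). CG13196, an uncharacterised gene on the fusion cell list, fell by 3.57 on the log2 scale (SE 0.14, limma adjusted p = 0.000166). Genes of the luminal chitin matrix fell as well: Gasp and obst-B, which encode chitin-binding proteins, by 1.53 (SE 0.18) and 1.46 (SE 0.11), and Cda4, a chitin deacetylase gene, by 0.97 (SE 0.16). Other genes of tube formation were higher in trh null embryos, among them dpy, which encodes a giant apical matrix protein (1.36, SE 0.27), and the transcription factor genes grh (0.80, SE 0.14) and rib (0.69, SE 0.14). The calls for Cda4, dpy, grh and rib were lost with any 1 trh null array left out (limma adjusted p from 0.0584 to 0.115). That for dpy was also lost without wild type replicate 1 (adjusted p = 0.0602), and that for rib without wild type replicate 3 (adjusted p = 0.0631).

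The 3 tracheal lists held 43 measured genes, of which 7 fell, 6 rose and 30 did not pass the test; adjusted over the list alone, 11 fell and 6 rose. In the list for patterning and branching, btl fell, rib and grh rose, and 13 of 16 members did not pass (limma's camera test, adjusted p = 0.699; the counts were the same adjusted over the list alone). The calls for rib and grh were lost with any 1 trh null array left out (limma adjusted p from 0.0653 to 0.115), and that for btl was not. That list passed as higher without wild type replicate 1 (camera adjusted p = 0.0417). Its direction turned to lower without wild type replicate 2, where 2 members fell (median log2 difference -0.15 in place of 0.11, camera adjusted p = 0.588). The log2 differences between trh null and wild type of those 13 ran from -0.25 for sty, the Sprouty gene, to 0.87 for salm, a zinc finger gene (SE 0.12 and 0.30). They were 0.19 for vvl, a POU factor gene, 0.17 for tgo, the bHLH-PAS partner gene of trh, 0.24 for bnl, the FGF ligand gene, 0.03 for kni, -0.02 for knrl, 0.29 for salr, -0.01 for bs, -0.12 for apt, 0.04 for tkv, 0.48 for dpp and -0.21 for Mipp1. With wild type replicate 2 left out, vvl, tgo, bnl and tkv changed sign (-0.15, -0.16, -0.08 and -0.20). The values were then 0.24 for kni, -0.38 for knrl, -0.25 for bs, 0.20 for dpp and 0.56 for salm. In that fit apt passed (-0.30, limma adjusted p = 0.0287), and salm did without wild type replicate 1 (1.18, limma adjusted p = 0.0289). In the fusion cell list CG13196 fell, dysf (0.54, SE 0.11) and shg, the E-cadherin gene (0.63, SE 0.14), rose, and 5 of 8 members did not pass (camera adjusted p = 0.643; 2 fell and 2 rose adjusted over the list alone). A second probe set for dysf fell by 0.37 on the log2 scale, and the mean over its probe sets did not pass (0.05, limma adjusted p = 0.761). All probe sets for dysf lay below the median of all probe sets, 6.19, in both genotypes. Of the fusion cell list 2 fell and 2 rose without wild type replicate 2 (median log2 difference -0.25 in place of -0.06). In the luminal matrix list Gasp, obst-B, Cda4, the chitin synthase gene kkv and dyl fell, dpy and uif rose, and 12 of 19 members did not pass (8 fell and 2 rose adjusted over the list alone). Of that list 10 fell and 2 rose without wild type replicate 2. Its camera test gave a lower level in trh null embryos (median log2 difference -0.25, adjusted p = 0.00967), but adjusted p = 0.661 with an estimated correlation. A second probe set for uif fell by 0.90 on the log2 scale, from 5.68 to 4.78, also below that median. The calls for dysf, shg and dyl were lost with any 1 trh null array left out (limma adjusted p from 0.0783 to 0.137). Those for dysf and dyl were also lost without wild type replicate 1 (0.0530 and 0.0574), and that for shg without wild type replicate 3 (0.0721). Over the 3 lists together the median log2 difference was -0.04. It was -0.24 without wild type replicate 2, where 14 members fell and 6 rose. The RNA came from whole embryos, so none of these values can be assigned to tracheal cells. A change confined to those cells could be hidden by signal from other tissues. A gene that did not pass is therefore not shown to be independent of trh.

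**Figure D1:**
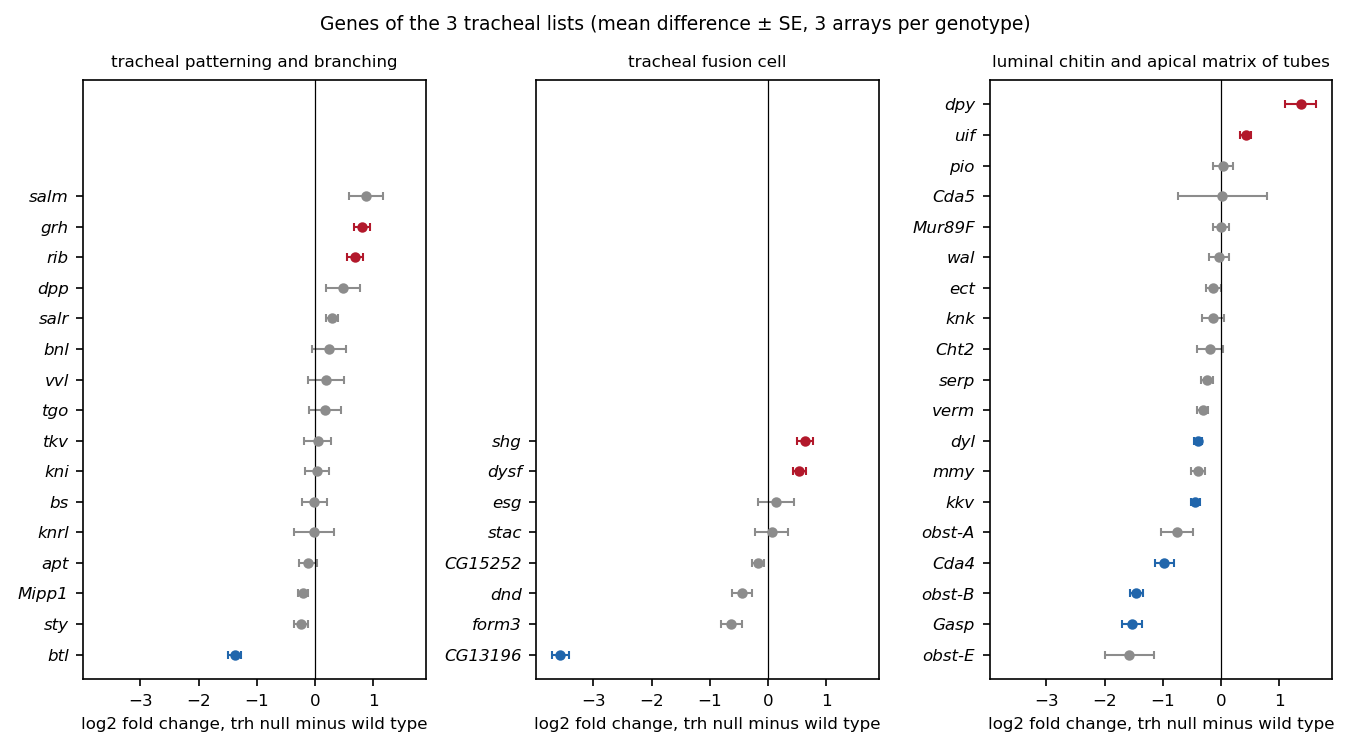
Log2 fold change of trh null over wild type (horizontal axis) for each measured gene of the 3 tracheal lists, with points for the mean difference and bars for its standard error (3 arrays per genotype); blue genes fell, red genes rose and grey genes did not pass the test. CG13196 (-3.57) lies lowest, followed by Gasp, obst-B and btl among the genes that fell, while 30 of the 43 genes are grey.

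Of 24 measured genes of the Osiris family, a tandem family of insect membrane proteins, 11 fell in trh null embryos, none rose and 13 did not pass; adjusted over the list alone, 12 fell and 1 rose. Osi19, Osi20, Osi18, Osi15 and Osi9 fell by 4.13 to 6.25 on the log2 scale, while Osi2 fell by 1.38 and Osi14 by 0.55. Osi6 was bright in both genotypes, at 14.57 in wild type and 14.54 in trh null embryos, and Osi7 was 10.73 and 11.58 (limma adjusted p = 0.0954). The camera test placed the family lower (median log2 difference -0.37, adjusted p = 6.09e-07), with adjusted p = 0.553 with an estimated correlation. Among 100 genes of cuticle protein families, 9 fell, 1 rose and 90 did not pass, and the counts were the same when adjusted over the list alone. Cpr64Ad fell by 4.52 (SE 0.67) and Cpr64Ab fell by 3.82 (SE 0.50) on the log2 scale. TwdlQ fell by 3.01 (SE 0.34) and Cpr66D fell by 1.99 (SE 0.30), while Cpr78E rose. The camera adjusted p was 0.000473 (median -0.28), and adjusted p = 0.778 with an estimated correlation. Of 9 genes of cuticle tanning and the epidermal barrier, snu, an ABC transporter gene, and snsl fell by 2.69 and 1.26, and 7 did not pass (3 fell adjusted over the list alone; camera adjusted p = 0.0302, and adjusted p = 0.650 with an estimated correlation). Leaving out wild type replicate 2 gave a median of -0.24 for the Osiris family and -0.47 for cuticle proteins. In that fit 44 cuticle protein genes fell in place of 9, and 5 of the tanning and barrier genes fell. The calls were lost for Cpr64Ad without trh null replicate 2 (limma adjusted p = 0.0556), for Cpr66D without trh null replicate 3 (0.0584) and for snsl with any 1 trh null array left out (0.0658 to 0.0749). The camera call for tanning and barrier genes was lost without wild type replicate 1 (adjusted p = 0.0758). The actin control probe sets, which differ in their distance from the 3' end of the transcript, had a log2 difference of 3' over 5' signal of 1.36 ± 0.09 on wild type arrays and 0.76 ± 0.03 on trh null arrays (SD, n = 3).

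**Figure D2:**
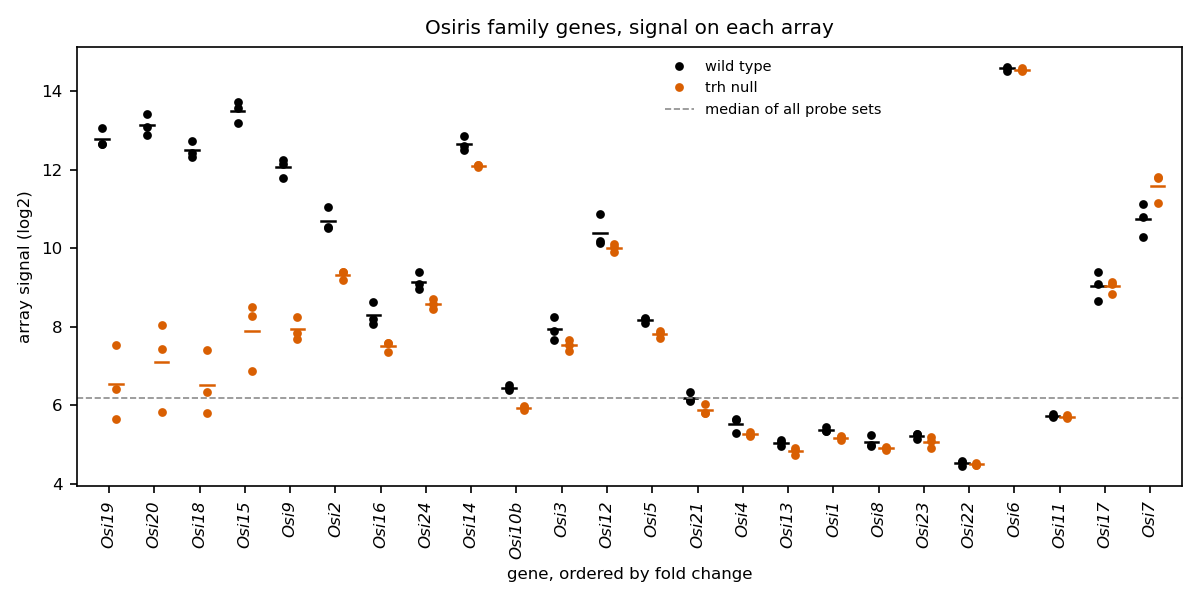
Log2 array signal (vertical axis) of the 24 measured Osiris genes (horizontal axis, ordered by fold change), with 1 point per array and a bar at each genotype's mean; the dashed line marks the median of all probe sets, 6.19. In the 5 genes on the left the wild type arrays lie well above the trh null arrays, and Osi6 is near 14.6 in both genotypes.

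In trh null embryos 8 of 10 measured glycolysis genes, 7 of 15 somatic muscle genes and 2 of 5 heat shock genes fell. The camera test placed each list lower (adjusted p = 4.31e-06, 0.00390 and 0.0186), with adjusted p = 0.553, 0.760 and 0.553 with an estimated correlation. None of the glycolysis genes rose (9 fell adjusted over the list alone): Gapdh1 fell by 1.36 (SE 0.12), Tpi by 1.11 (SE 0.12), Pgk by 1.09 (SE 0.17) and Pglym78 by 0.72 (SE 0.12) on the log2 scale. Of the muscle genes 1 rose and 7 did not pass (8 fell and 1 rose adjusted over the list alone). The muscle genes that fell included TpnC73F, for troponin C (5.04-fold), Prm, for paramyosin (2.85-fold), and up, for troponin T (2.20-fold); Msp300, a giant nesprin gene, rose 2.24-fold by its brightest probe set, but the mean over its 6 probe sets did not pass (0.29 on the log2 scale, limma adjusted p = 0.278). Of the heat shock genes Hsp26 and Hsp68 fell by 2.65 (SE 0.48) and 2.35 (SE 0.36), and 3 did not pass (3 fell adjusted over the list alone). The median log2 difference was -0.56 for glycolysis, -0.78 for muscle and -0.79 for heat shock. The calls for Pgk, Pglym78, Hsp68 and Msp300 were lost with any 1 trh null array left out (limma adjusted p from 0.0534 to 0.0954). That for Hsp26 was lost without wild type replicate 1, trh null replicate 2 or trh null replicate 3 (0.0602, 0.0889 and 0.0880). Wild type replicate 2 stood apart from the other wild type arrays, and without it 9 glycolysis, 11 muscle and 4 heat shock genes fell.

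In trh null embryos 5 of 14 early segmentation genes, 5 of 12 heart and amnioserosa genes, 2 of 13 cell cycle and DNA replication genes and 4 of 26 secretory pathway genes rose. The camera test placed each list higher (adjusted p = 0.000964, 0.00717, 0.00717 and 0.0246), with adjusted p = 0.661, 0.650, 0.553 and 0.778 with an estimated correlation. None of the early segmentation genes, which are used mostly before stage 11, fell (6 rose adjusted over the list alone): ftz rose by 1.22 (SE 0.16), Kr by 1.14 (SE 0.18), sna by 0.86 (SE 0.19), slp2 by 0.77 (SE 0.17) and twi by 0.63 (SE 0.11) on the log2 scale. In the list for heart and amnioserosa none fell (6 rose adjusted over the list alone), and those that rose were the GATA partner gene ush (1.33, SE 0.26), the T-box genes Doc1 (1.11, SE 0.08), Doc2 (1.04, SE 0.19) and Doc3 (0.89, SE 0.11), and pnr. Heart genes of that list were among the 7 that did not pass. In the list for the cell cycle and DNA replication PCNA (0.64, SE 0.10) and RnrL (0.50, SE 0.09) rose and 11 did not pass, with the same counts adjusted over the list alone (6 rose without wild type replicate 2). The secretory pathway genes that rose were Sec24AB, Sec24CD, Sec31 and Spase25, and 22 did not pass, with the same counts adjusted over the list alone. The median log2 difference was 0.47 for early segmentation (0.21 without wild type replicate 2), 0.43 for heart and amnioserosa, 0.40 for the cell cycle and 0.17 for the secretory pathway (0.28 without wild type replicate 2). The calls for sna, slp2, ush, RnrL and the 4 secretory genes were lost without wild type replicate 3 (limma adjusted p from 0.0529 to 0.0944) and with any 1 trh null array left out (0.0666 to 0.166). Those of the secretory genes were also lost with cyclic loess (0.0627 to 0.104). With any 1 trh null array left out those for Doc2 and PCNA were lost (0.0614 to 0.0899), that for Doc2 also without wild type replicate 1 (0.0539), and that for Kr without trh null replicate 2 or 3 (0.0533 and 0.0597). The camera call for the secretory pathway was lost without wild type replicate 3 (adjusted p = 0.389). In the fit without wild type replicate 2, 12 of its genes rose and 1 fell. All 4 lists were higher while the signal ratio of 3' over 5' control probe sets was lower on trh null arrays, for GAPDH 0.84 ± 0.13 in place of 1.12 ± 0.08 on the log2 scale (SD, n = 3).

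**Figure D3:**
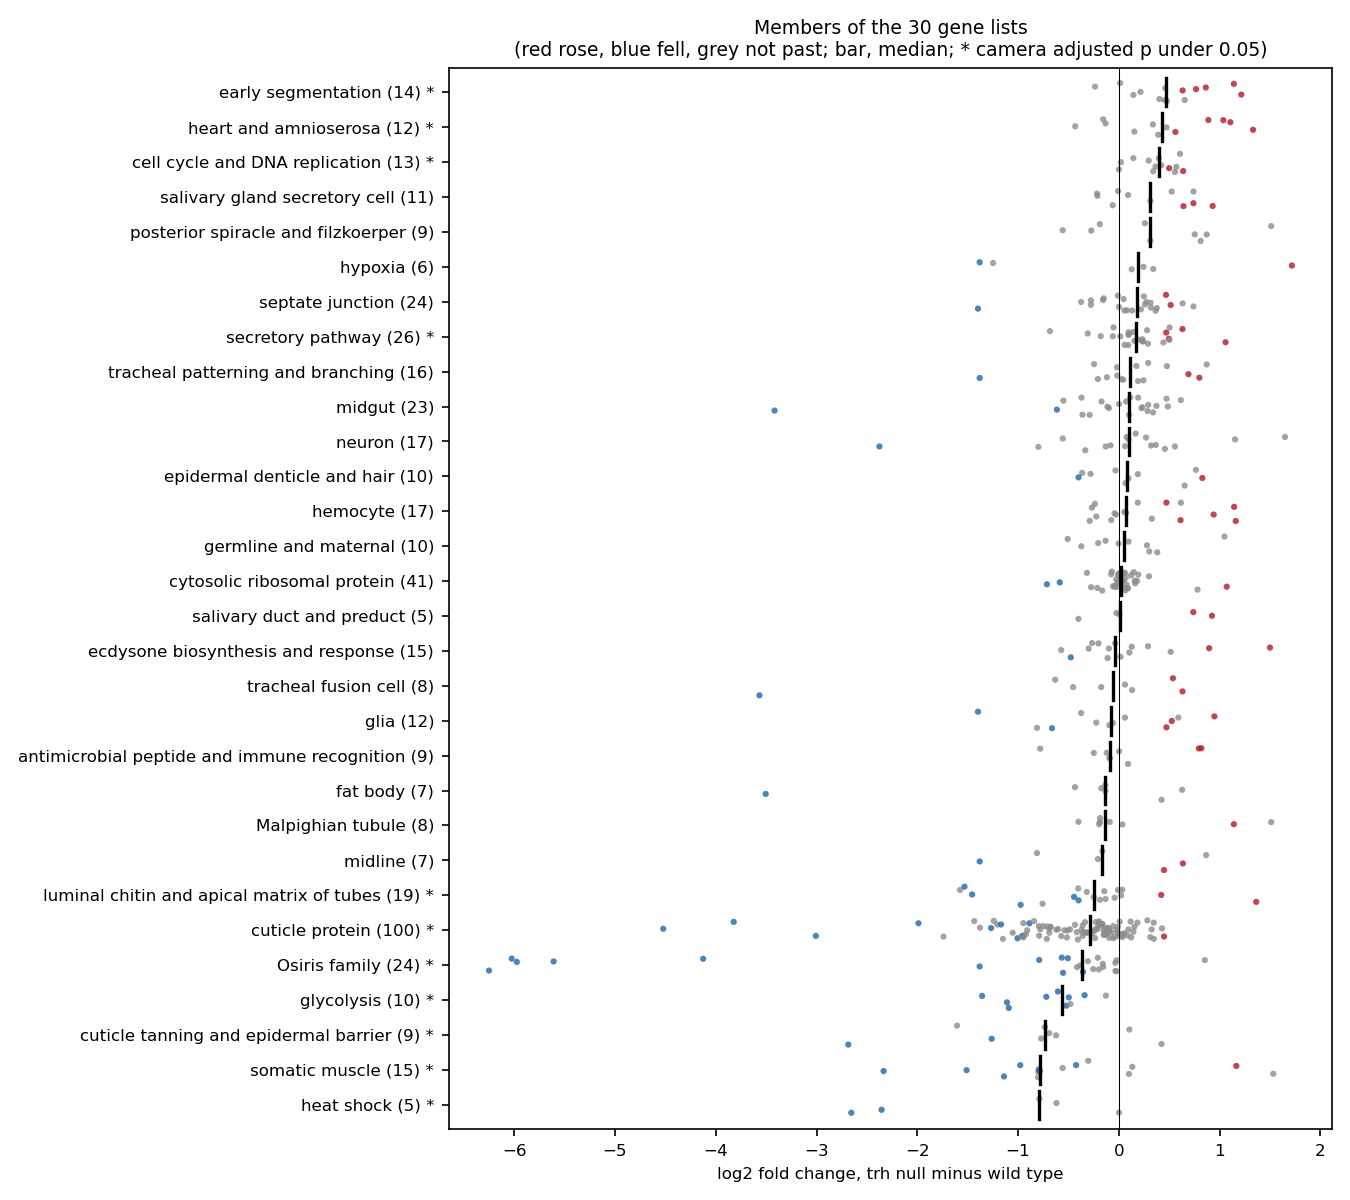
Log2 fold change of trh null over wild type (horizontal axis) for every measured member of the 30 gene lists (rows, with the number of members), in red where the gene rose, blue where it fell and grey where it did not pass; the black bar is the list's median and an asterisk marks a camera adjusted p under 0.05. The marked lists with the lowest medians are heat shock (-0.79) and somatic muscle (-0.78), and early segmentation has the highest median (0.47).

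Some genes of the salivary gland and duct rose in trh null embryos; trh is also used in the duct. In the salivary gland list fkh (0.93, SE 0.14), sens (0.74, SE 0.13) and hkb (0.64, SE 0.14) rose on the log2 scale, and 8 of 11 did not pass (4 rose adjusted over the list alone; camera adjusted p = 0.101). In the salivary duct list btd (0.92, SE 0.14) and eyg (0.74, SE 0.11) rose and 3 of 5 did not pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.488). None of 9 genes of the posterior spiracle and filzkörper passed, over all probe sets or over the list alone (camera adjusted p = 0.488). The log2 differences there were 1.51 for ct (SE 0.57, limma adjusted p = 0.152) and 0.87 for salm (SE 0.30, limma adjusted p = 0.119). They were 0.82 (limma adjusted p = 0.0130) and 0.56 (limma adjusted p = 0.0603) without wild type replicate 2, where 3 of the 9 rose. In the fit without wild type replicate 1 salm passed (1.18, limma adjusted p = 0.0289). The calls for sens and hkb were lost without wild type replicate 3 (limma adjusted p = 0.0530 and 0.0695) and with any 1 trh null array left out (0.0716 to 0.135). Those for fkh and btd were lost without trh null replicate 2 or 3 (0.0557 to 0.0603), and that for eyg without trh null replicate 1 or 3 (0.0577 and 0.0653). The salivary gland list passed as higher without wild type replicate 1 (camera adjusted p = 0.0344) and without trh null replicate 1 (adjusted p = 0.0469).

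Markers of other tissues changed one by one, and their lists did not pass the camera test. Snap25, a synaptic vesicle fusion gene, fell 5.19-fold and was the only one of 17 neuron genes to pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.816). With wild type replicate 2 left out, 6 neuron genes fell and 3 rose. The camera direction of that list then turned to lower (adjusted p = 0.308). Of 12 glia genes 3 rose, including gcm2 (0.95, SE 0.10) and Gs2 (0.53, SE 0.13), and nrv2 and alrm fell by 1.40 (SE 0.12) and 0.66 (SE 0.09); the counts were the same adjusted over the list alone (camera adjusted p = 0.816). Of 17 hemocyte genes 5 rose, including the scavenger receptor gene Sr-CI (1.16, SE 0.17), NimC4 (1.14, SE 0.26), the peroxidasin gene Pxn (0.94, SE 0.08) and PPO2 (0.61, SE 0.09), with the same counts adjusted over the list alone (camera adjusted p = 0.101). In the fat body list svp, a nuclear receptor gene, fell 11.3-fold by its brightest probe set, and 6 of 7 did not pass (camera adjusted p = 0.101). Another probe set for svp rose by 0.79 on the log2 scale, from 3.91 to 4.70. Both values lay below the median of all probe sets, 6.19. In the midgut list the protease genes Jon44E and zetaTry fell by 3.42 (SE 0.30) and 0.61 (SE 0.14) and 21 of 23 did not pass (camera adjusted p = 0.816). Kr was the 1 of 8 Malpighian tubule genes that rose (camera adjusted p = 0.959). None of 10 germline and maternal genes passed (camera adjusted p = 0.759). The log2 differences of tud and bcd were 1.05 (SE 0.57, limma adjusted p = 0.298) and -0.51 (SE 0.65, limma adjusted p = 0.676). With any 1 trh null array left out the calls for Gs2, zetaTry and NimC4 were lost (limma adjusted p from 0.0678 to 0.173). They were also lost without wild type replicate 1 (0.0531, 0.0749 and 0.0866), and those for Gs2 and zetaTry without wild type replicate 3 (0.0742 and 0.0595). Those for Sr-CI, PPO2 and Kr were lost without trh null replicate 2 or 3 (0.0533 to 0.0597). The value of bcd was 0.16 without wild type replicate 3 (limma adjusted p = 0.856). The value of tud was 0.34 without wild type replicate 2 and then passed (limma adjusted p = 0.0268). In the same fit the fat body list passed as lower (camera adjusted p = 0.0377). Of the tubule genes 2 then rose and 2 fell, and the camera direction turned to lower (adjusted p = 0.588). Of the hemocyte genes 6 rose and 2 fell in that fit. The hemocyte list passed as higher and the midgut list as lower without trh null replicate 1 (camera adjusted p = 0.0407 and 0.0276). Adjusted over the list alone, the counts for fat body, midgut, tubule and germline were the same.

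In the septate junction list pck (0.47, SE 0.09) and M6 (0.51, SE 0.12) rose, nrv2 fell, and 21 of 24 did not pass (camera adjusted p = 0.367). Of 10 genes of denticles and hairs ovo, the shavenbaby gene, rose by 0.83 (SE 0.11) on the log2 scale and dyl fell by 0.40 (SE 0.07) (camera adjusted p = 0.759). Of 7 midline genes the EGF pathway genes S and spi rose by 0.64 and 0.45 and btl fell (camera adjusted p = 0.850; 2 rose and 2 fell adjusted over the list alone). Of 6 hypoxia genes sima, the HIF-1 alpha gene, rose by 1.72 (SE 0.39) and btl fell (camera adjusted p = 0.930). Of 9 immune genes Drs and PGRP-SB1 rose by 0.79 and 0.82 (camera adjusted p = 0.816). Of 15 ecdysone genes Hr4 rose 2.83-fold and shd by 0.90 (SE 0.17) on the log2 scale, and EcR fell by 0.48 (SE 0.10) (camera adjusted p = 0.816). Of 41 cytosolic ribosomal protein genes RpS28-like rose by 1.07, RpLP2 and RpS10a fell by 0.59 and 0.71, and 38 did not pass (camera adjusted p = 0.816; 1 rose and 1 fell adjusted over the list alone). In the remaining lists of this group the counts were the same adjusted over the list alone. The calls for pck, spi and sima were lost without wild type replicate 3 (limma adjusted p = 0.0630, 0.0575 and 0.0624) and with any 1 trh null array left out (0.0874 to 0.144). Those for shd, EcR and RpS10a were lost with any 1 array but wild type replicate 2 left out (0.0502 to 0.166), and that for M6 with any 1 but that and trh null replicate 1 (0.0837 to 0.164). The call for dyl was lost without wild type replicate 1 (0.0574) and with any 1 trh null array left out (0.0870 to 0.0953), that for S without trh null replicate 2 or 3 (0.0542 and 0.0600), and those for ovo and RpLP2 without trh null replicate 3 (0.0509 and 0.0556). Leaving out wild type replicate 2 gave 4 septate junction genes that rose and 2 that fell. In that fit 4 ribosomal protein genes rose and 3 fell, and 2 denticle, 2 hypoxia and 3 ecdysone genes fell. The camera direction of the denticle list then turned to lower (adjusted p = 0.796). The median and the mean log2 difference had opposite signs in the hypoxia (0.19 and -0.03), immune (-0.09 and 0.04), midgut (0.10 and -0.09), Malpighian tubule (-0.14 and 0.20) and ecdysone (-0.04 and 0.09) lists, and the camera direction followed the mean in each.

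Control probe sets also differed between the genotypes. Spike-in polyadenylated Bacillus transcripts were 4.33-fold brighter on wild type arrays (7.99 ± 0.61 against 5.87 ± 0.17 on the log2 scale, SD, n = 3), and the bacterial hybridization spike-ins bioB, bioC and bioD 2.20-fold brighter. The 18S rRNA signal was 16.0-fold higher on wild type arrays at the 5' probe set and 4.16-fold higher at the middle one, and 1.37-fold higher at the 3' one (exact two-sided permutation p = 0.5). For the spike-ins and the 5' and middle 18S probe sets the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. Wild type replicate 2 correlated with the other wild type arrays at 0.976 and 0.979 across probe sets, which are not independent replicates, against 0.994 between wild type replicates 1 and 3. Among trh null arrays the correlations ran from 0.995 to 0.998.

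**Figure D4:**
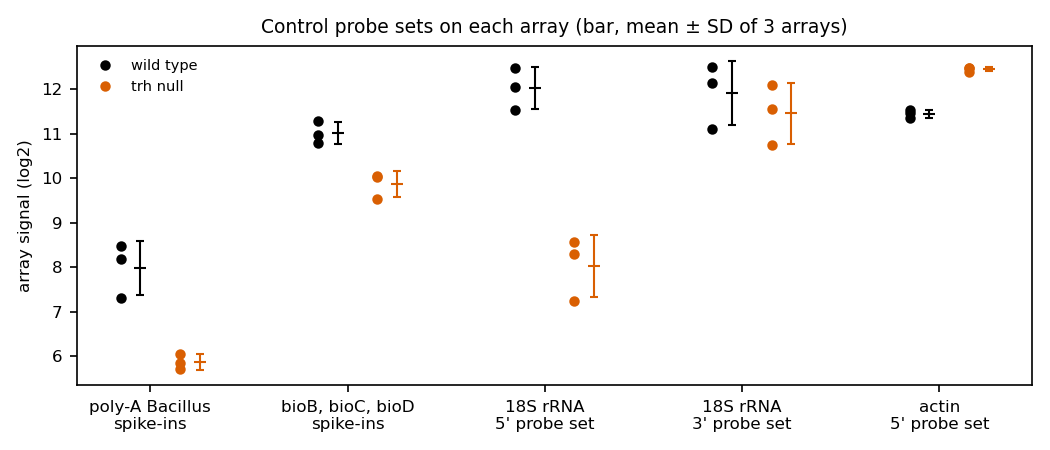
Log2 array signal (vertical axis) of 5 sets of control probe sets (horizontal axis) on each wild type (black) and trh null (orange) array, with bars for the mean ± SD of 3 arrays. The spike-ins and the 18S rRNA 5' probe set lie higher on all 3 wild type arrays, the actin 5' probe set lies higher on all 3 trh null arrays, and the 18S 3' probe set overlaps.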

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

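The tests on gene length in wild type replicate 2 and on chromosome 3 were chosen after the values they explain had been seen, and the trend removal on gene length after the control probe sets had been seen.

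A control probe set outside the gene tests differed between genotypes: the 5' probe set of actin was 1.00 higher on the log2 scale on trh null arrays, with every trh null array above every wild type array (exact two-sided permutation p = 0.1, the smallest that 3 arrays against 3 allow).

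The lower level of Osiris and cuticle protein genes in trh null embryos was weighed against 3 explanations. Strain background on chromosome 3, weighed below for other genes only, was not tested for these lists and stays open as well. Loss of signal from long genes in wild type RNA would raise short genes after normalization. A trend on gene length, introns included, did not account for the pattern. With that trend removed, the median log2 difference of the 124 genes was -0.283 after -0.312 before. It lay below the lowest of 10000 random lists matched on signal and length (-0.14). Those lists held random genes and may vary too little to stand for gene families. Shorter wild type RNA was not tested in this way and stays open. The actin 3' minus 5' log2 difference was higher on wild type arrays (1.36 against 0.76). Both biological explanations stay open. If trh null embryos were younger on average, genes that come on late in tissues without trh could be lower too. The somatic muscle list was lower (median -0.78), but the neuron list had a median of 0.097 (-0.07 without wild type replicate 2). The test therefore does not decide. Outside that test, the early segmentation and cell cycle lists were higher (median 0.47 and 0.40), the direction that younger embryos could give. Neither of these 2 list calls held with an estimated correlation. With fry, early segmentation and somatic muscle did not pass (adjusted p = 0.0669 and 0.0672), while the cell cycle list did (0.0367). As the last stage, the sample descriptions give 17 for wild type and 16 for trh null embryos. The labels give 16 for both. Loss of tracheal cells and of trh-dependent expression could lower them as well; the 3 tracheal lists together had a median of -0.0411 over members that went both ways (-0.24 without wild type replicate 2). The direction of limma's camera test over their 43 genes was lower (adjusted over the 2 fits, adjusted p = 0.0834 with all arrays and adjusted p = 0.00426 without wild type replicate 2), so this test does not decide, and neither explanation excludes the other.

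Wild type replicate 2 lay apart from the other arrays: it had an array weight of 0.136, and the median SD per probe set was 0.164 over wild type arrays against 0.0803 over trh null arrays. Shorter RNA in that sample than in the other wild type samples is argued against by its actin and GAPDH probe sets. Their 3' minus 5' log2 differences of 1.3016 and 1.03 lay inside the ranges of the other arrays (0.741 to 1.46 and 0.688 to 1.18). Those ranges span both genotypes, which differ. Within wild type the values were the lowest, against 1.46 and 1.17 for replicate 1 and 1.31 and 1.18 for replicate 3. A lower signal of genes with long transcription units may be part of it: the deviation of this array from the other wild type arrays had a Spearman rho of -0.3381 with gene length across 11883 genes, which are not independent replicates, against -0.01 for the difference of wild type replicates 1 and 3. The deviation of trh null replicate 1 from the other trh null arrays had a rho of -0.18, so a weaker trend was not confined to this array. No biological explanation was tested for a single array.

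Some genes were near background in one genotype and at least 4-fold higher in the other, and strain background on chromosome 3, which carries trh and is homozygous in the mutant embryos, is a candidate explanation for part of them. Near background here means a mean log2 signal of the lower genotype below the median of all probe sets, 6.19. Outside the Osiris and cuticle protein lists there were 45 such genes, and 29 (64.4%) lay on chromosome 3 against 44.4% of the other genes (odds ratio 2.27, 95% interval 1.19 to 4.48, Fisher's exact test, two-sided p = 0.00983). Of the 35 that fell 22 lay there (odds ratio 2.12, Fisher's exact p = 0.0395). Of the 10 that rose 7 did (odds ratio 2.92, Fisher's exact p = 0.121). Over the 1664 genes that passed and were compared in this way the difference was small and its interval held 1: 46.3% against 44.2% (odds ratio 1.09, 95% interval 0.98 to 1.21, Fisher's exact test, two-sided p = 0.099). Among the 45, ry on arm 3R, mutant alleles of which mark many laboratory stocks of this chromosome, fell from 8.55 ± 0.10 to 4.52 ± 0.06. Also on 3R, svp fell by 3.50 by its brightest probe set, while Hsc70-2, GstD4, GstD7 and Ugt37A2 rose. The set also held the falls of CG31559, apn, Cht5 and CG11786 on 3R and of CG12009 and Snap25 on 3L. Those of tpr, CG13196 and Jon44E were in it as well and lay on 2R. Neighbouring genes of 1 family count separately here, so the p-value may be too small. The cuticle genes Ccp84Ag on 3R and Twdlbeta on 2R, which the list pattern had missed, were still in the set. Regulation by trh of genes on this chromosome stays open and was not tested.

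With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2219 probe sets, 1492 probe sets with at least 1.5-fold change and 7 tracheal genes that fell; the highest count in any of the other splits was 0 for each, so 1 of the 10 splits gave as many.

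The control probe sets separate the arrays in the same way as genotype. The 18S rRNA 5' signal was 16.0-fold and the polyadenylated spike-in signal 4.33-fold higher on wild type arrays, and the labels used here give no processing batch that holds both genotypes. RNA amount, labelling and hybridization therefore cannot be told apart from genotype for the counts and lists of the report.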

How the results depend on the processing

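The removal of the gene length trend was chosen after the control probe sets had been seen; all other alternatives were set before the data were examined. No named gene or list that passed changed sign under any alternative. Of 1871 values of named genes under an alternative 1587 kept their side of the threshold, 276 lost it (46 with unmoderated variances, Twdlbeta among them, 41 with the replicate block, 12 with cyclic loess, none without wild type replicate 2 and 13 to 46 without any other 1 array) and 8 gained it, and of 540 list values 510 kept it, 21 lost it and 9 gained it.

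The 2219 changed probe sets became 949 with unmoderated variances, 6003 with array weights and 738 at an adjusted p under 0.01, and 704 to 5001 with single arrays left out. The 1492 changed at least 1.5-fold became 644 with unmoderated variances, 607 at 2-fold and 692 to 2194 with single arrays left out. The 7 tracheal genes that fell became 16 with array weights and 4 to 14 with single arrays left out. Among the fits with 1 array left out the highest counts came without wild type replicate 2, and the lowest without trh null replicate 3 (for tracheal genes, without any 1 trh null array). A stricter threshold lowers a count by construction; for the other settings the cause was not tested. Trend and robust prior, quantile normalization, median centring, cyclic loess, the filter on dim probe sets and the length correction kept these counts within 1.5 times.

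With the replicate number as a replicate block 726 probe sets passed, 725 of them at least 1.5-fold. No pairing by number was seen: deviations of arrays with the same number correlated at -0.37, -0.06 and -0.05 across probe sets. Those of arrays with unlike numbers correlated at -0.18 to 0.37. With 3 arrays per genotype a weak pairing cannot be excluded. With an estimated correlation 0 of the 11 list calls held (adjusted p from 0.553 to 0.778; camera with the preset correlation called 11 and fry 7 of these, while fry also called salivary duct, hemocyte and fat body, with adjusted p = 0.0346, 0.0157 and 0.000469), and all 11 held without wild type replicate 2 and with the length trend removed. Lists that camera called and fry did not were cuticle proteins and the secretory pathway (fry adjusted p = 0.251 for each), somatic muscle (0.0672) and early segmentation (0.0669). Cyclic loess ended the camera calls for the secretory pathway (adjusted p = 0.0596) and cuticle tanning (0.0619), the filter on dim probe sets that for the secretory pathway (0.0675), and array weights that for early segmentation (0.0621). Leaving out wild type replicate 1 ended the camera call for cuticle tanning (adjusted p = 0.0758), and leaving out wild type replicate 3 ended that for the secretory pathway (0.389). Lists gained a camera call without wild type replicate 1 (tracheal patterning, 0.0417; salivary gland, 0.0344), without wild type replicate 2 (fat body, 0.0377) and without trh null replicate 1 (salivary gland, 0.0469; hemocyte, 0.0407; midgut, 0.0276). The transcript of trh and its alternatives were not run, since no probe set was named for it alone. Signal near background limits dim genes, where fold changes are understated.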

Other observations

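All families described here were picked after their values had been seen, so their camera p-values cannot serve as tests. Genes of the E(spl) and Bearded families, which respond to Notch signalling, had higher levels in trh null embryos: 12 of 13 measured members rose, none fell and 1 did not pass (median log2 difference 1.24, limma's camera test, adjusted over the 4 families picked, p = 1.12e-09; adjusted p = 0.236 with an estimated correlation). E(spl)mdelta-HLH rose by 1.82 (SE 0.21), E(spl)m4-BFM by 1.55 (SE 0.20) and Ocho by 1.44 (SE 0.20), while BobA differed by 1.00 (SE 0.34, limma adjusted p = 0.119). Without wild type replicate 2 all 13 rose. These genes lie in clusters on chromosome 3.

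Genes of the GstD and cytochrome P450 families, taken by symbol, went both ways. Of 11 glutathione transferase genes of the GstD family, GstD3, GstD4 and GstD7 rose, by 1.89, 2.23 and 2.05, GstD1 and GstD10 fell by 0.58 and 0.67, and 6 did not pass (camera adjusted p = 0.328). Of 81 cytochrome P450 genes 4 rose and 11 fell (9 and 18 without wild type replicate 2; median -0.10, camera adjusted p = 0.0272, and adjusted p = 0.295 with an estimated correlation). Of 5 cuticle genes that the symbol pattern of the cuticle protein list had missed, Twdlbeta fell by 4.74, Ccp84Ag fell by 3.19 and Ccp84Ae fell by 1.86 on the log2 scale, and Ccp84Ac and Twdlalpha did not pass (camera adjusted p = 0.00377, and adjusted p = 0.295 with an estimated correlation).

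Some genes had probe sets that passed in opposite directions. One probe set for teq fell by 2.19 on the log2 scale (SE 0.28) and another rose by 2.19 (SE 0.10), and for ScsbetaG 1 probe set fell by 1.06 (SE 0.21) and another rose by 1.85 (SE 0.19). Groups did not overlap for 6760 probe sets, 36.0% of those tested, where chance gives 10%.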
